A study of Mus musculus with 6 samples.

How the data were processed

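The data were RNA-seq measurements of 6 mouse samples, 3 WT and 3 Igf1rKO, taken on day 4 of pregnancy. Per the labels' protocols, uterine horns were digested in trypsin, luminal epithelial cells were squeezed out of the horn, and polyA RNA was sequenced on Illumina libraries. The labels call the cells epithelium and, in another field, give the tissue as decidua. Samples were grouped by the genotype in their labels, and column numbers were matched to the numbers in the sample titles, which assumes that the authors did not renumber them.

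Per the submitters' processing notes, STAR and edgeR were used with build mm10. Versions, annotation, strandedness and the order of steps are not given in the sources used here. The deposited table holds FPKM values per library and gene, per the file headers. It also holds the authors' ratio (fold) of Igf1rKO over WT, and the authors' p-value for each gene; whether that p-value is adjusted is not stated. The table has 4 FPKM columns per genotype, and 2 of its per-sample columns match no sample and were not used in any step. The authors' fold and p-value can rest on those columns too: for 28.1% of the tested genes the authors' deposited fold differed by more than 1.1-fold from the ratio of means over the 6 libraries. These columns were used for Igf1r only.

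FPKM values are not counts, so the count test planned before the data were examined was replaced by the fallback planned with it. FPKM multiplied by the gene's exon length in GENCODE release M21 (mm10) fell on multiples of 1 step per library. From 99.2% to 99.3% of the values up to 20 reads were whole within 0.1. The steps gave 29389000 to 32304400 reads per library, and showed that the authors had scaled by library sizes of 30255200 to 33338200 reads, with factors of 0.948 to 1.03. Of the tested genes 98.3% had an exon length. At this depth the spread between libraries, not read counting, limits most genes; paralogs, and genes that overlap on either strand, are uncertain because the counting is not described.

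Values were analysed as log2(FPKM + 1), and a fold change is on that scale, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, 13800 of 54096. Genotypes were compared with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with a trended and robust prior and Benjamini-Hochberg adjustment at 0.05. The single value of Igf1r also had a two-sided exact permutation test. A total of 28 gene lists (18 on biology, 10 on cell composition) were fixed before the data were examined. The list of blastocyst and male embryo markers had 0 members at the minimum level and was not tested. Each other list was tested with camera at a preset correlation of 0.01, adjusted over the lists of its kind. It was tested again with an estimated correlation and with fry. With the preset correlation 12 lists passed, with an estimated correlation 0, and with fry 1. Counts of members were adjusted over all genes and over the list alone. Of the tested composition markers, 9 of 15 luminal, 2 of 12 glandular, 4 of 20 stromal and 7 of 24 immediate early members also stood in another list.

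Named genes were fixed by a rule: Igf1r, up to 12 genes per direction past the adjusted threshold with separated libraries and a level of at least 5, and up to 4 members with the smallest p-value per list. The text gives fewer than 4 for some lists. As limma called 0 genes (1004 higher and 940 lower at an unadjusted p under 0.05), the part of the rule for genes past the threshold named none. A rule added after the data were seen (unadjusted p under 0.01, mean of at least 5 FPKM, separated libraries, 8 per direction) supplied the genes in the closing section. Areg, Cyp26a1, Foxo1, Ltf and Igkc were chosen after their values were seen.

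The procedure was tested on simulated data for Igf1rKO against WT over 13570 genes, drawn from the real means, spreads and depths with 200 changed genes. It recovered 10.0% of genes changed 2-fold and 47.0% of those changed 4-fold, with 5 false calls among 66. A planted list of 40 genes at 0.5 of their level was called by camera (adjusted p = 3.023e-42), 32 of its members passed over the list alone, and 0 of 50 unchanged lists were called. The simulated genes were independent, so this does not test camera under correlation.

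Alternatives covered scaling, pseudocounts of 0.1 and 5, filters on low values, the spread estimate, a block for replicate number, a test against a 1.5-fold change, and leaving out each library. The following were added after the data were seen: limma-voom on the recovered reads, library quality weights, and leaving out WT 2 and Igf1rKO 1 together. Libraries of the same genotype were compared for duplication, and the closest pair, WT 1 and WT 3, differed by a chi-square of 47.9 per gene, far above sampling noise.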

Results

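RNA was sequenced from the luminal epithelium of mouse uteri on day 4 of pregnancy, the cell sheet that lines the uterine cavity and that the embryo meets first. The epithelium came from 3 wild-type (WT) samples and from 3 samples in which Igf1r, the gene of the receptor for insulin-like growth factor 1, was knocked out (Igf1rKO). Expression was given in FPKM, fragments scaled by gene length and library size, for 54096 genes per library. The low values fell on whole numbers of reads, from which 29389000 to 32304400 reads per library were recovered. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The series title places the work in the question of whether lysosomes and protein degradation are activated in the epithelium at implantation, and the genotype comparison asks what the epithelium expresses without Igf1r.

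Igf1r itself was lower but not absent in the knockout libraries. The gene (Entrez 16001) lies on chromosome 7 of mm10, from 67952827 to 68233668 on the + strand, and is protein coding. Its level was 5.73, 4.69 and 4.53 FPKM in WT 1, 2 and 3, and 4.40, 2.32 and 2.34 FPKM in Igf1rKO 1, 2 and 3. The means were 4.98 ± 0.655 (SD, n = 3) and 3.02 ± 1.20 (SD, n = 3) FPKM, so that the knockout mean was 60.6% of the WT mean. All 3 knockout values lay below all 3 WT values, though Igf1rKO 1 came close to WT 3. The difference did not pass the limma test over all genes (log2 fold change −0.61, SE 0.233, adjusted p = 0.334), and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The deleted exons are not given in the labels, and a value over the whole gene also counts reads from exons outside a deletion, so this level checks the labels only in part. The authors' deposited table gave a ratio of 0.663 with p = 0.0965 for Igf1r, where the 6 libraries analysed here gave 0.606.

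In several gene groups, members passed the threshold with p adjusted over their own list, with no adjustment over the lists tested. Of 41 tested genes of DNA replication and cell division, 34 fell with p adjusted over the list alone, with the replication licensing gene Mcm5 at 19.1 ± 7.24 FPKM in WT and 4.17 ± 2.58 in Igf1rKO (SD, n = 3). In cholesterol and fatty acid synthesis 10 of 32 tested genes fell by that adjustment, with Cyp51, a sterol demethylase of the cholesterol pathway, at 19.5 ± 2.92 and 6.03 ± 1.60 FPKM. Among gland markers 8 of 12 rose, with Foxa2, a transcription factor of uterine glands, at 1.60 ± 1.41 and 10.8 ± 6.44 FPKM, and among target genes of the FOXO transcription factors, which insulin and IGF signalling holds out of the nucleus, 3 of 24 rose, with Txnip at 50.8 ± 25.3 and 162 ± 12.3 FPKM. By limma 0 genes of these lists passed with p adjusted over all genes, where without WT 2 the counts were 5, 2, 1 and 4. As sets they gave adjusted p = 0.504, 0.275, 0.427 and 0.504 with an estimated correlation. The FOXO count over the list alone was 0 without any one library other than WT 2. The gland count was 0 without any one of WT 1, WT 3 or Igf1rKO 1.

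All 41 tested genes of the cell cycle and DNA replication list had a fold change below 0, with a median log2 fold change of −1.14. By limma, 34 of them fell with p adjusted over the list alone and 0 with p adjusted over all genes (5 without WT 2). The smallest p-values belonged to Ccne1, the cyclin that drives entry into S phase (log2 fold change −2.21, SE 0.325), and to Mcm6 (−1.29, SE 0.245), Mcm5 (−2.02, SE 0.400) and Mcm2 (−1.35, SE 0.273), subunits of the replicative helicase. Their adjusted p over the list alone was 0.0108. The list as a set passed camera with its preset correlation (adjusted p = 2.724e-24) and did not with an estimated one (adjusted p = 0.504 with an estimated correlation). The count was 15 without WT 1, 18 without Igf1rKO 1 and 15 without Igf1rKO 3, and 1 against a fold of 1.5. Markers of endothelium and leukocytes had median log2 fold changes of −0.69 and −0.82, and Igf1rKO 1 was the lowest library for both. Their library medians overlapped between the genotypes. For endothelium WT 3 (−0.60) lay below Igf1rKO 2 (−0.31) and Igf1rKO 3 (−0.50). For leukocytes WT 1 (−0.58) lay below Igf1rKO 2 (−0.54) and Igf1rKO 3 (−0.56). Without WT 2 the median log2 fold changes were −0.65 and −0.14.

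In the cholesterol and fatty acid synthesis list, 30 of 32 tested genes had a fold change below 0, with a median log2 fold change of −0.46. By limma, 10 fell with p adjusted over the list alone and 0 over all genes, where without WT 2 Cyp51 (adjusted p = 0.0468) and Msmo1 (0.0412) passed. Cyp51 (log2 fold change −1.56, SE 0.211), Msmo1, another demethylating enzyme of the pathway (−1.28, SE 0.206), Srebf2, the transcription factor that drives cholesterol synthesis (−0.85, SE 0.139), and Hmgcr, its rate-limiting enzyme (−0.79, SE 0.135), shared an adjusted p over the list alone of 0.00554. Srebf2 fell from 16.6 ± 1.09 to 8.76 ± 0.776 FPKM and Hmgcr from 7.57 ± 0.310 to 3.95 ± 0.379 FPKM (SD, n = 3), by that adjustment. The set passed camera (adjusted p = 1.066e-09; adjusted p = 0.275 with an estimated correlation), and fry, which asks whether the genes of the list move on balance one way, gave an adjusted p of 0.0213, the only list it called. The count was 6 without WT 1, 4 among genes with a mean of at least 5 FPKM, and 1 against a fold of 1.5. The library median of gland markers (median log2 fold change 1.56) was higher in every knockout library than in any WT library. Of the 12 members, 7 were separated in this way. Medians of leukocyte (−0.82) and endothelial markers (−0.69) were below 0, but their library medians overlapped between the genotypes.

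**Figure D1:**
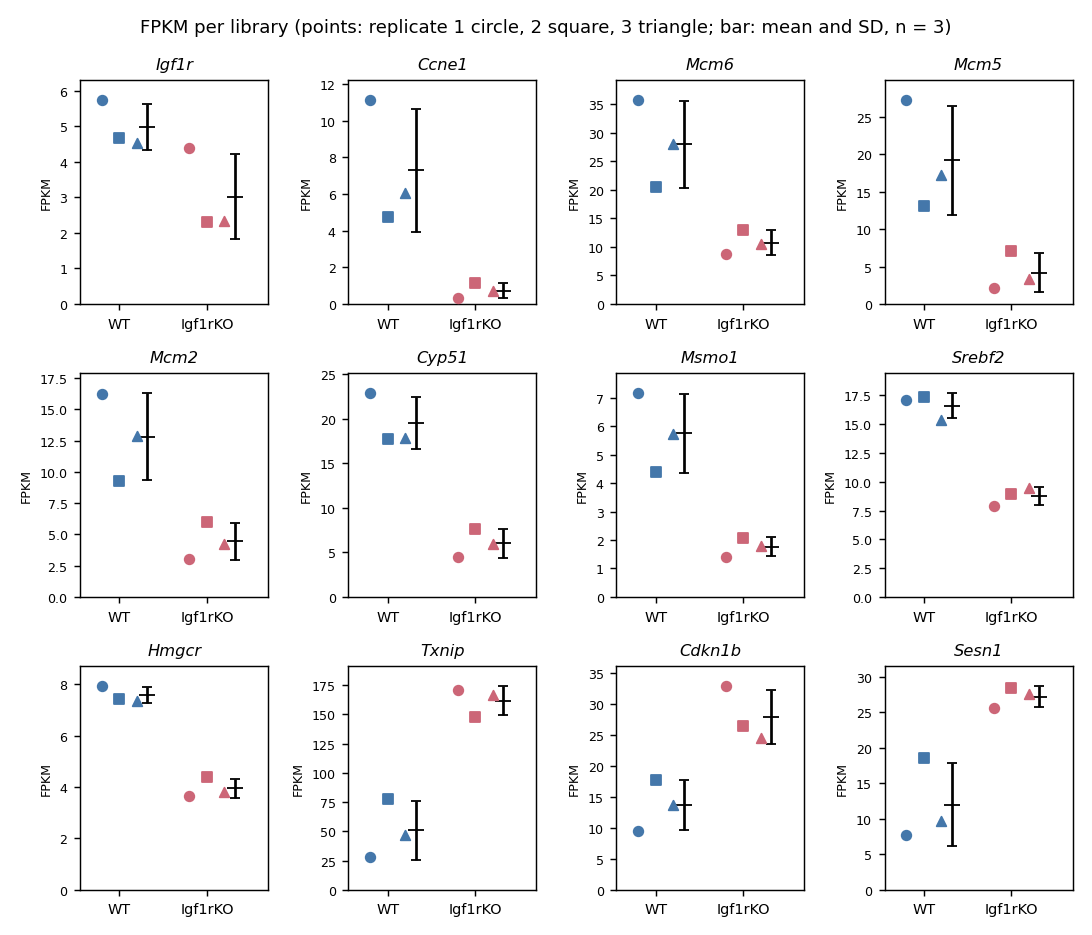
FPKM per library (linear axes from 0) of Igf1r and of the genes with the smallest p-values in the cell cycle, cholesterol and FOXO lists. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), and the bars give the mean and SD of 3 libraries; every knockout value lies below every WT value for the cell cycle and cholesterol genes shown, and above for Txnip, Cdkn1b and Sesn1.

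Of 24 tested FOXO target genes, 19 had a fold change above 0, with a median log2 fold change of 0.36. By limma, 3 rose with p adjusted over the list alone (each with an adjusted p of 0.0457) and 0 over all genes (4 without WT 2). These were Txnip, an inhibitor of thioredoxin and glucose uptake (log2 fold change 1.77, SE 0.366), Cdkn1b, the cell cycle inhibitor p27 (1.01, SE 0.246), and Sesn1, a stress-induced inhibitor of mTORC1 (1.21, SE 0.303). The set passed camera (adjusted p = 0.00130; adjusted p = 0.504 with an estimated correlation). The count of 3 was fragile: it was 0 under median-of-ratios or library-total scaling, with no filter on low values, and without any one of WT 1, WT 3, Igf1rKO 1, Igf1rKO 2 or Igf1rKO 3, and 7 without WT 2. The library median of gland markers (median log2 fold change 1.56) was higher in every knockout library than in any WT library. The medians of mitochondrially encoded transcripts (0.38) and leukocyte markers (−0.82) came from library medians that overlapped between the genotypes.

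Over all 13800 genes tested, limma called 0 genes higher and 0 lower in Igf1rKO at an adjusted p under 0.05, and the smallest adjusted p was 0.145. At an unadjusted p under 0.05, 1004 genes were higher and 940 lower, 14.1% of the genes where chance alone gives 690 genes. limma-voom on the recovered reads also called 0 and 0. In 1605 genes all 3 knockout libraries lay above all 3 WT libraries, and in 1183 below, together 20.2% of the genes where chance gives 10%. The WT libraries did not group together: WT 2 correlated with WT 1 and WT 3 at r = 0.864 and 0.842 across genes, which are not independent replicates, where WT 1 and WT 3 reached 0.972 and WT 2 reached 0.919 with Igf1rKO 2. Without WT 2, 51 genes were called higher and 145 lower at an adjusted p under 0.05. Of these 196 genes, 195 kept their direction with all 6 libraries, and the other, Rgs6, was not tested there. With all 6 libraries, 114 had an unadjusted p under 0.05 by limma and 87 had separated libraries. The fits share every library but WT 2, so a kept direction is not independent support. All calls given without WT 2 rest on WT 1 and WT 3, the most alike pair of libraries, as the WT group. The narrow spread of that pair makes calls easier. Without WT 3 limma called 1 higher and 1 lower, and without Igf1rKO 1 or Igf1rKO 3 it called 1 higher and 0 lower in each case.

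**Figure D2:**
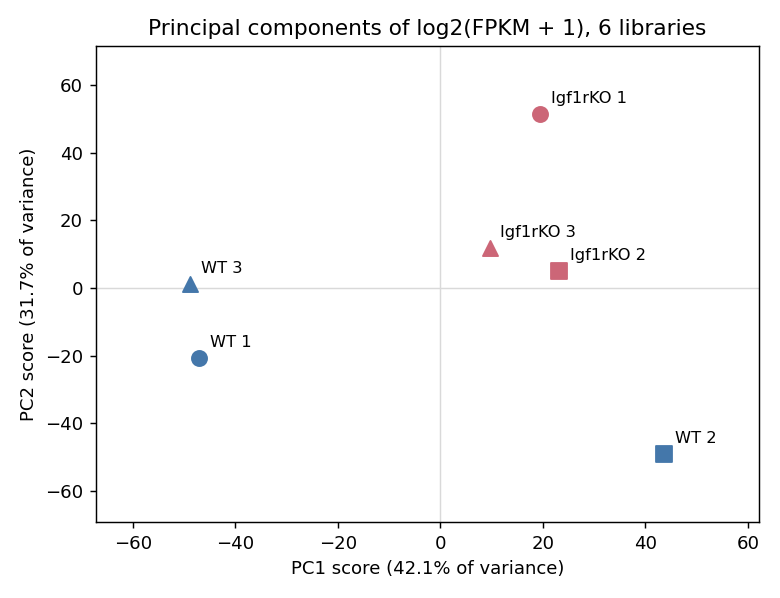
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) over 13800 genes (blue WT, red Igf1rKO, shapes for replicate numbers), with the percentage of variance on each axis. WT 1 and WT 3 sit together at the left, WT 2 lies at the lower right, and the 3 knockout libraries lie between them on PC1, which holds 42.1% of the variance.

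The lysosomal genes, the subject named in the series title, showed no shared direction that held in all settings. Among 68 tested lysosomal hydrolases and membrane proteins, 49 had a fold change below 0, with a median log2 fold change of −0.19. By limma, 1 gene fell with p adjusted over the list alone: Gla, the alpha-galactosidase of the lysosome, at 8.02 ± 1.45 FPKM in WT and 3.09 ± 0.585 in Igf1rKO (SD, n = 3; adjusted p over the list alone 0.0384). Lamp2, a main membrane protein of the lysosome, was measured at 157 ± 26.2 and 97.0 ± 12.7 FPKM, Gns at 37.2 ± 2.34 and 27.9 ± 1.39, and the protease Ctsb at 546 ± 186 and 293 ± 13.1 (SD, n = 3), without passing. The list passed camera downward (adjusted p = 0.00574; adjusted p = 0.770 with an estimated correlation). This call rested on WT 2, without which the test turned upward with an adjusted p of 0.741. WT 2 had the highest library median for this list (0.36) and for leukocyte markers (0.99). A link between them was not tested. The count over the list alone was 0 without any one of WT 1, WT 3, Igf1rKO 1 or Igf1rKO 2, 2 lower without WT 2, and 1 lower and 1 higher without Igf1rKO 3.

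The proton pump that acidifies lysosomes did not differ as a group. Of 21 tested V-ATPase subunits, 11 had a fold change below 0, with a median log2 fold change of −0.02 (camera adjusted p = 0.863). Atp6v1g2 (log2 fold change 0.95, SE 0.225) and Atp6v0e2 (1.52, SE 0.443) had higher means in Igf1rKO, and Atp6v0a2 (−0.50, SE 0.142) and Tcirg1 (−0.51, SE 0.161) lower ones, and by limma 0 passed over the list alone, with 2 higher and 2 lower at an unadjusted p under 0.05. The 37 autophagy genes and TFEB family members had a median of 0.11 (camera adjusted p = 0.0974), with 0 calls over the list alone and 3 genes higher at an unadjusted p under 0.05 by limma. Among them Gabarapl1 was at 29.6 ± 2.91 FPKM in WT and 70.9 ± 23.5 in Igf1rKO, and Mitf, a relative of TFEB, at 1.46 ± 1.12 and 5.13 ± 1.41 (SD, n = 3). The autophagy set passed camera upward without WT 3 (adjusted p = 0.0124) or Igf1rKO 2 (adjusted p = 0.0410). In all libraries it had an adjusted p = 0.770 with an estimated correlation. Without WT 2, limma called 2 V-ATPase genes higher and 1 lower, and 1 autophagy gene higher and 1 lower, over the list alone.

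Proteasome subunits and genes of the unfolded protein response had lower medians in Igf1rKO. Of 41 proteasome subunits, 35 had a fold change below 0, with a median log2 fold change of −0.26 (camera adjusted p = 5.599e-04; adjusted p = 0.770 with an estimated correlation). The smallest p-values were those of Psmd1 (−0.62, SE 0.189) and Psmd14 (−0.68, SE 0.214). Of 28 genes of the unfolded protein response, the programme that meets protein overload in the endoplasmic reticulum, 24 had a fold change below 0, with a median of −0.40 (camera adjusted p = 4.312e-04; adjusted p = 0.770 with an estimated correlation). Dnajc3 was at 53.5 ± 9.16 FPKM in WT and 27.6 ± 9.35 in Igf1rKO, and Sdf2l1 at 27.6 ± 2.11 and 12.7 ± 7.34 (SD, n = 3). In both lists limma called 0 genes over the list alone, with 3 and 7 genes lower at an unadjusted p under 0.05. Without WT 2 it called 6 proteasome subunits and 1 gene of the unfolded protein response lower, and without Igf1rKO 2 it called 5 of the latter. With WT 2 and Igf1rKO 1 both left out, the unfolded protein response list lost its camera call (adjusted p = 0.146), as it did with library quality weights (adjusted p = 0.226). The genotypes overlapped in both lists. The proteasome median of WT 2 (−0.35) lay below those of Igf1rKO 2 (−0.26) and Igf1rKO 3 (−0.11). The unfolded protein response median of Igf1rKO 2 (−0.08) lay above that of WT 3 (−0.09). The library medians of gland markers (median log2 fold change 1.56) lay apart between the genotypes, while those of leukocyte markers (−0.82) overlapped.

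Genes of uterine receptivity went both ways. Of 40 tested implantation genes, 19 had a fold change above 0 and 21 below (median log2 fold change −0.05, camera adjusted p = 0.789). The prostaglandin synthase Ptgs2 was at 9.88 ± 3.90 FPKM in WT and 1.52 ± 1.16 in Igf1rKO, and the ligand Wnt7b at 7.66 ± 5.60 and 0.651 ± 0.157, whereas the gland transcription factor Foxa2 was at 1.60 ± 1.41 and 10.8 ± 6.44, and the peroxidase Gpx3 at 12.5 ± 3.47 and 57.7 ± 32.3 (SD, n = 3). All 4 stopped short of the threshold over the list alone (adjusted p = 0.0506 by limma), and 7 genes were higher and 6 lower at an unadjusted p under 0.05. Without WT 2, 7 implantation genes were called higher and 9 lower over the list alone, and without Igf1rKO 3, 3 higher and 2 lower.

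Hormone and cytokine targets were likewise mixed. The 24 progesterone-responsive genes had a median log2 fold change of −0.30 (camera adjusted p = 0.185), with Tsc22d3 (25.5 ± 1.78 FPKM in WT, SD, n = 3, and 56.6, 42.1 and 72.2 FPKM in the knockout libraries) and Gata2 (1.17, SE 0.427) above 0, and Fst (−1.39, SE 0.395) and Acod1 (−1.31, SE 0.443) below. The 25 oestrogen-responsive genes had a median of −0.40 but a mean of −0.01 (camera adjusted p = 0.650), and the members with the smallest p-values were above 0: Greb1 (1.76, SE 0.486), the oestrogen receptor gene Esr1 (0.80, SE 0.229), Padi1 (1.98, SE 0.563) and the water channel Aqp5 (2.94, SE 0.871). Of 28 genes responsive to LIF, the cytokine needed for implantation, and its mediator STAT3, 23 had a fold change below 0, with a median of −0.45 (camera adjusted p = 0.0615). Timp1 (−1.81, SE 0.517) and Tnfrsf12a (−1.97, SE 0.570) were among them, whereas Hp (3.46, SE 0.932) and Msx1 (1.16, SE 0.340) were above 0. In these 3 lists limma called 0 genes over the list alone in all libraries, with 7, 8 and 4 genes at an unadjusted p under 0.05. Without WT 2 it called 9 progesterone, 10 oestrogen and 14 LIF and STAT3 genes, and the LIF and STAT3 list passed camera downward (adjusted p = 1.729e-05). That list also passed camera downward under library-total scaling (0.0363), with a pseudocount of 5 (0.0405), with no filter on low values (0.0220) and with the replicate block (0.0250). The same held with library quality weights (5.561e-04), with WT 2 and Igf1rKO 1 both left out (2.866e-05) and without Igf1rKO 3 (0.0102). In all libraries the list had an adjusted p = 0.770 with an estimated correlation. Without Igf1rKO 3 limma called 5 oestrogen genes higher and 1 LIF and STAT3 gene higher, and without Igf1rKO 2 it called 1 progesterone gene higher.

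The components of IGF and insulin signalling showed no group difference. Of 32 tested, 14 had a fold change above 0 and 18 below (median log2 fold change −0.08, camera adjusted p = 0.555). The FOXO genes Foxo4 (log2 fold change 0.66, SE 0.148) and Foxo3 (0.96, SE 0.296), and the receptor substrate gene Irs1 (1.26, SE 0.419), had higher means in Igf1rKO, while Foxo1 had a lower one (−0.58, SE 0.466). Without WT 2, Foxo3 passed over all genes as higher (adjusted p = 0.0419) and Foxo1 as lower (0.0433). The binding protein gene Igfbp3 had a lower one, at 78.6 ± 59.9 FPKM in WT and 8.82 ± 7.67 in Igf1rKO (SD, n = 3). By limma, 0 of the 32 passed over the list alone, with 3 higher and 4 lower at an unadjusted p under 0.05, and without WT 2 the counts over the list alone were 1 higher and 2 lower. Of 38 junction and polarity genes, limma called 1 lower over the list alone: the tight junction gene Cldn1, at 22.2 ± 3.91 FPKM in WT and 6.63 ± 2.14 in Igf1rKO (SD, n = 3; adjusted p over the list alone 0.0189). The junction list had a median of 0.15 (camera adjusted p = 0.185), and 0 members were called without WT 2 or WT 3. Without Igf1rKO 2 the junction list passed camera upward (adjusted p = 0.0141; in all libraries adjusted p = 0.812 with an estimated correlation), and without Igf1rKO 3 limma called 1 member higher besides the 1 lower.

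Among metabolic lists, cytosolic ribosomal proteins had a higher median. Of 80 tested, 76 had a fold change above 0, with a median log2 fold change of 0.40 (camera adjusted p = 4.050e-07; adjusted p = 0.770 with an estimated correlation). The call was lost with library quality weights (adjusted p = 0.0714). Rplp2 (0.78, SE 0.303) had the smallest p, and by limma 0 passed over the list alone, with 1 gene higher at an unadjusted p under 0.05. The library medians of the ribosomal list ranged from −0.50 in WT 2 to 0.76 in Igf1rKO 3, relative to the WT mean. The genotypes overlapped, with Igf1rKO 1 (0.21) below WT 1 (0.26) and WT 3 (0.22). Without WT 2 the median log2 fold change was 0.15. Gland markers (1.56) and mitochondrially encoded transcripts (0.38) also had median log2 fold changes above 0. The 23 glycolysis genes had a median of −0.36 (camera adjusted p = 0.0676), with the lactate transporter gene Slc16a3 (−0.98, SE 0.255) below 0 and Hk1 (0.53, SE 0.185) above. The 75 genes of oxidative phosphorylation had a median of 0.06 (camera adjusted p = 0.185), led by Ndufa6 (0.71, SE 0.230), and the 32 interferon response genes a median of −0.11 (camera adjusted p = 0.216), led by Stat2 (−0.51, SE 0.205). In these 3 lists limma called 0 genes over the list alone, with 7, 2 and 3 genes at an unadjusted p under 0.05, and without WT 2 it called 5 glycolysis genes. Camera called glycolysis lower under library-total scaling (adjusted p = 0.0438) or without Igf1rKO 3 (adjusted p = 0.0320). It called oxidative phosphorylation higher without Igf1rKO 1 (adjusted p = 0.00164) or WT 1 (adjusted p = 0.00934), and the interferon list lower without WT 1 (adjusted p = 0.00125) or Igf1rKO 3 (adjusted p = 0.00391). In all libraries the 3 lists gave adjusted p = 0.770, 0.841 and 0.812 with an estimated correlation.

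**Figure D3:**
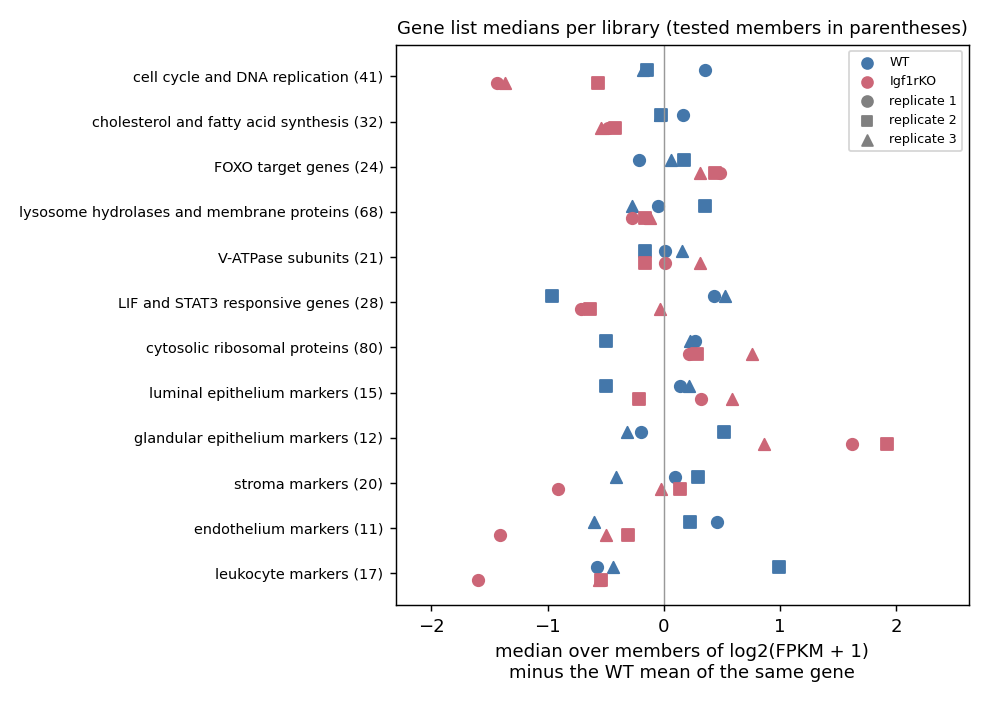
Median over the tested members of each list of log2(FPKM + 1) minus the WT mean of the same gene, per library (blue WT, red Igf1rKO, shapes for replicate numbers, number of tested members in parentheses). Among the lists drawn, the knockout libraries lie apart from all WT libraries for the cell cycle, cholesterol, FOXO and gland lists. WT 2 lies outside the other WT libraries in most of the lists drawn. It is furthest from the WT mean for leukocyte markers (0.99) and LIF and STAT3 genes (−0.97), with others such as ribosomal proteins (−0.50) and gland markers (0.51).

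The makeup of the preparations was read from marker lists. Glandular markers were higher in the knockout: 11 of 12 tested had a fold change above 0, with a median log2 fold change of 1.56, and limma called 8 higher over the list alone and 0 over all genes (1 without WT 2). Foxa2 (log2 fold change 2.16, SE 0.501), the progenitor factor Sox9 (1.85, SE 0.444), the gland secretory gene Spink1 (1.54, SE 0.394) and the WNT target Axin2 (0.73, SE 0.198) had the smallest p-values. The list passed camera (adjusted p = 1.181e-05; adjusted p = 0.427 with an estimated correlation). The count over the list alone was 0 without any one of WT 1, WT 3 or Igf1rKO 1, 3 without Igf1rKO 2, and 9 higher and 1 lower without WT 2. Luminal markers showed no shared direction with all 6 libraries (15 tested, median 0.14, camera adjusted p = 0.582). Krt18 was at 218 ± 68.9 FPKM in WT and 413 ± 147 in Igf1rKO (SD, n = 3), and limma called 0 of the list over the list alone, with 1 gene higher and 1 lower at an unadjusted p under 0.05. Without WT 2 it called 1 luminal marker lower, and without Igf1rKO 2 it called 1 higher and the list passed camera upward (adjusted p = 0.0454; in all libraries adjusted p = 0.885 with an estimated correlation).

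Markers of other cell types were present in every library. All 17 tested leukocyte markers had a fold change below 0 (median log2 fold change −0.82, camera adjusted p = 0.00167; adjusted p = 0.537 with an estimated correlation), with the macrophage gene Lyz2 at 723 ± 295 FPKM in WT and 260 ± 154 in Igf1rKO, and C1qb at 94.2 ± 64.3 and 32.4 ± 18.5 (SD, n = 3). That call was lost without WT 2 (adjusted p = 0.545) and with library quality weights (0.481), and the list turned upward with WT 2 and Igf1rKO 1 both left out (0.447). Of 11 endothelial markers, 10 had a fold change below 0 (median −0.69, camera adjusted p = 0.00505; adjusted p = 0.537 with an estimated correlation), among them Pecam1 (−1.17, SE 0.494), and the call was lost without WT 2 (adjusted p = 0.199), without Igf1rKO 1 (0.0975), without both (0.447), with the filter of 5 FPKM (0.0937) and with library quality weights (0.0538). The 20 stroma markers had a median of −0.32 (camera adjusted p = 0.317), with Vim at 154 ± 20.7 and 116 ± 30.5 FPKM (SD, n = 3). The camera test of stroma markers was downward and past the threshold without WT 3 (adjusted p = 0.00701), Igf1rKO 2 (adjusted p = 0.0454) or Igf1rKO 3 (adjusted p = 0.0490). It turned upward without Igf1rKO 1 (0.241) or WT 2 (0.667), and passed upward with both left out (0.00721). In all libraries the stroma list had an adjusted p = 0.885 with an estimated correlation. In these 3 lists limma called 0 genes over the list alone, with 3, 1 and 0 genes lower at an unadjusted p under 0.05.

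Of 6 tested smooth muscle markers, limma called 2 higher over the list alone, Cnn1 (0.0783 ± 0.0214 FPKM in WT and 3.73 ± 3.15 in Igf1rKO) and Actg2 (0.112 ± 0.0856 and 6.03 ± 6.37, all SD, n = 3). The list's median was −7.399e-04 and its mean 0.62, and camera, pointing upward, gave an adjusted p of 0.326, and 0.0460 with no filter on low values (adjusted p = 0.537 with an estimated correlation). The count was 0 without any one of WT 1, WT 2 or WT 3 and 1 without Igf1rKO 1. All 5 tested erythroid markers had a fold change above 0 (median 1.11, camera adjusted p = 0.00995; adjusted p = 0.537 with an estimated correlation), with Hba-a1 at 35.8 ± 26.5 and 89.2 ± 48.6 FPKM (SD, n = 3), and that call was lost without WT 2 (adjusted p = 0.0821) or Igf1rKO 2 (adjusted p = 0.0722). Without WT 3 limma called 4 erythroid markers higher over the list alone, and without Igf1rKO 1 all 5. All 13 mitochondrially encoded transcripts had a fold change above 0 (median 0.38, camera adjusted p = 0.00387; adjusted p = 0.537 with an estimated correlation), with mt-Nd6 at 1228 ± 294 and 1980 ± 377 FPKM (SD, n = 3). Of 24 immediate early and heat shock genes, which can mark handling of tissue, limma called 2 higher over the list alone, Ier3 (1.49, SE 0.286) and Jun (0.69, SE 0.150), while the list had a median of −0.40 (camera adjusted p = 0.582). Without any one of WT 1, Igf1rKO 1, Igf1rKO 2 or Igf1rKO 3 that count was 0, without WT 3 it was 1, and without WT 2 it was 2 higher and 5 lower, with camera downward (adjusted p = 0.0202; in all libraries adjusted p = 0.885 with an estimated correlation). None of the 15 markers of blastocysts and of male embryos reached the minimum level for testing, and the highest single value was 1.18 FPKM, of Elf5 in WT 2.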

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

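The alternatives with quality weights, with voom and with WT 2 and Igf1rKO 1 both left out were chosen after seeing the data. The planned edgeR, DESeq2 and glmTreat fits were not run, because the table holds FPKM; limma's test against a fold of 1.5 stood in for the last. Igf1r has no value under the filter of 5 FPKM, which removes it. In the other settings its log2 fold change stayed below 0, and its adjusted p passed only with quality weights (−0.83, adjusted p = 0.0321; elsewhere 0.0726 to 0.812, and 0.999998 for Igf1r against a fold of 1.5). The causes of the changes below were not tested, except where fewer genes or libraries entered.

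Genes higher and lower at the adjusted threshold numbered 0 and 0 by limma (1004 and 940 unadjusted) under every scaling, pseudocount, filter, spread estimate, voom and fold test. They were 203 and 233 with WT 2 and Igf1rKO 1 both left out, 876 and 1137 with quality weights (weights from 0.264 for WT 2 to 4.43 for WT 1, estimated from the same 6 libraries), and 0 to 51 and 0 to 145 with 1 library left out. Same-numbered libraries had correlations of deviations of −0.05, 0.28 and 0.05, so the numbers were not taken to pair them; with the replicate block limma called 0 and 0 (815 and 853 unadjusted), and camera called the LIF and STAT3 list (adjusted p = 0.0250). Of the 6 libraries, only WT 2 and Igf1rKO 2 correlated best with their own number.

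Over the list alone, cell cycle members lower numbered 15 with the filter of 5 FPKM, 1 against a fold of 1.5, and 15 to 41 with 1 library left out. Cholesterol members numbered 20 with quality weights, 4 with that filter, 1 against that fold, and 6 to 13. FOXO members numbered 6 with both libraries left out, 10 with quality weights, 0 under library-total or median-of-ratios scaling, no filter or the fold test, and 0 to 7. Gland members numbered 0 to 9. Of the 12 lists called by camera, 0 passed with an estimated correlation and 1 with fry.

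The lysosome list had an adjusted p of 0.770 with an estimated correlation, 0.476 with fry, 0.656 with quality weights, and 0.625 with both libraries left out, where it turned upward; with 1 library left out it ran from 4.209e-06 to 0.741. V-ATPase turned upward with no filter (0.863) and ran from 0.409 to 0.975. Other lists changed direction. With both libraries left out the adjusted p was 0.592 for junctions, 0.370 for interferon, 0.447 for leukocytes, 0.413 for luminal markers, 0.625 for oestrogen and 0.00721, upward, for stroma. With quality weights it was 0.817 for junctions and for oestrogen, 0.724 for interferon, 0.472 for luminal markers, 0.706 for oxidative phosphorylation and 0.747 for stroma. With the filter of 5 FPKM it was 0.707 for immediate early genes, 0.670 for oestrogen and 0.603 for smooth muscle, and with no filter 0.937 for IGF signalling. With 1 library left out the ranges were 0.0141 to 0.975 for junctions, 0.0202 to 0.969 for immediate early genes, 0.00125 to 0.975 for interferon, 0.0454 to 0.969 for luminal markers, 0.213 to 0.975 for oestrogen, 0.00164 to 0.768 for oxidative phosphorylation and 0.00701 to 0.667 for stroma.

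Among named genes, Ltf turned from −0.28 to 2.16 with both libraries left out and 1.86 with quality weights, and ran from −1.48 to 1.94 with 1 left out; Igkc ran from −0.54 to 2.05. Depth was even, so it does not separate the genotypes.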

Other observations

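The tests of explanations in this part (marker covariates, shares of gland, luminal and immune cells, a mislabelled library) and the counts of splits were chosen after the results they bear on were seen, as was the rule for the genes named first. That rule took genes with an unadjusted limma p under 0.01, a mean of at least 5 FPKM and separated libraries. It ranked them by fold change, so wide differences and separation come from the rule. Of all tested genes, 20.2% had separated libraries, where chance gives 10%. Beyond the lists, it named the genes below. Bpifb5, a gene of the BPI-fold family of secreted proteins, was at 0.932 ± 1.51 FPKM in WT and 27.1 ± 19.8 in Igf1rKO (SD, n = 3). The keratin gene Krt23 was at 5.32 ± 2.66 and 87.6 ± 63.0 FPKM, and the arginase gene Arg2 at 5.17 ± 4.01 and 30.3 ± 17.6. Slc5a1, the sodium-glucose cotransporter SGLT1, was at 40.7 ± 32.4 FPKM in WT and 1.62 ± 0.348 in Igf1rKO. Sftpd, the gene of surfactant protein D, was at 30.6 ± 18.3 and 2.63 ± 0.254 FPKM, the neurokinin B gene Tac2 at 15.2 ± 12.7 and 0.216 ± 0.176, and the sulfatase gene Sulf2 at 26.8 ± 6.05 and 6.39 ± 4.05. The matrix protease gene Mmp7 had a log2 fold change of −2.31 (SE 0.460). The same rule gave Krt83, Igkv4-78, Gkn3 and Ppp2r2b as higher and Ccl8 as lower. Uhrf1 (lower), Hp and Ptgs2, which it also gave, stand in the lists. None of the genes it gave passed the limma test over all genes (adjusted p from 0.241 to 0.275). Without WT 2, Slc5a1 (adjusted p = 0.0105), Tac2 (0.00983), Sftpd (0.0141), Gkn3 (0.0410) and Ptgs2 (0.0482) passed it, as Krt83 did without Igf1rKO 3 (0.0181).

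The lower level of cell cycle genes in Igf1rKO (median log2 fold change −1.14, median SE of a member 0.316, 34 members past the threshold over the list alone) may come from fewer dividing cells of another type in the knockout preparations. With the library median of stroma markers as a covariate the median was −0.97 (SE 0.313, 27 members past the threshold), and with leukocyte markers −1.09 (SE 0.385, 19 members). Most of the fall thus did not follow these markers. They follow all cells of a type and not the dividing ones, so the fits cannot decide about dividing stroma or leukocytes. With endothelial markers it was −0.78 (SE 0.363) and 0 members passed: about 0.682 of the size remained with a wider error, so a smaller endothelial share stays open. A lower rate of division in the epithelium without Igf1r, the difference that the design names, also stays open. It was not tested apart from fewer dividing cells of another type.

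Gland markers had higher values in Igf1rKO, with 11 of 12 fold changes above 0 and every knockout library median above every WT one. A smaller share of luminal cells would raise the markers of all other types alike, but gland medians exceeded those of 4 of 5 other cell-type lists (stroma, smooth muscle, endothelium and leukocytes) by more in every knockout library than in any WT library (for smooth muscle narrowly, 0.71 against 0.65), which argues against it as the whole cause. The exception was the erythroid list, whose median was also higher (1.11). Spink1, an abundant gland gene, was at 11.4 ± 3.74 FPKM in WT and 36.3 ± 14.8 in Igf1rKO (SD, n = 3). A larger share of gland cells and a higher expression per gland cell cannot be told apart. The members' log2 fold changes ran from −0.99 (Lgr5) to 3.14 (Cxcl15), with an SD of 1.08 beside a median SE of 0.52. They were thus unlike on this scale, but the scale understates the change of low genes. Genes also active outside glands would spread them too.

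WT 2 stood apart from WT 1 and WT 3: of 8386 genes with a mean of at least 5 FPKM, 176 were more than 2 higher on the log2 scale than in both and 78 more than 2 lower. A mislabelled knockout library stays open. WT 2 was placed over the 200 genes with the smallest p in a fit without it. On a scale from the knockout mean (0) to the mean of WT 1 and WT 3 (1), its median position was 0.0491. Each other library was placed on its own 200 genes, from a fit without it and without WT 2. Knockout libraries lay at 0.105 to 0.356. WT 1 and WT 3, each scaled against the other alone, lay at 0.909 and 0.791. A state shared by WT 1 and WT 3 alone would give such positions too. Of 9 lists whose medians parted WT 1 and WT 3 from the knockout libraries, WT 2 lay nearer to WT in 4 (cholesterol −0.02, knockouts −0.54 to −0.42). It lay nearer to the knockouts in 5 (LIF and STAT3 −0.97, knockouts −0.71 to −0.04). On the scale from 0 to 1, the gland (0.55), FOXO (0.49) and glycolysis lists (0.45) put WT 2 near the middle. The IGF list was parted only narrowly (WT 1 −0.008, Igf1rKO 2 −0.025). The Igf1r level of WT 2 (4.69 FPKM) lay between those of WT 3 (4.53) and WT 1 (5.73) and above the knockout libraries (4.40, 2.32 and 2.34). Of the 176 higher genes 139 were immunoglobulin genes, which took 3.07% of the reads in WT 2 against 0.0628% to 0.696% elsewhere. Leukocyte markers were highest there too, and more immune cells would give both. Igkc was at 13235 FPKM in WT 2, 634 in WT 1, 366 in WT 3, and 796, 3089 and 3247 in Igf1rKO 1, 2 and 3. The oestrogen-responsive gene Ltf was at 1235 FPKM in WT 2 and lower in WT 1 (12.6), WT 3 (9.80) and Igf1rKO 1, 2 and 3 (33.5, 74.1 and 38.1). Dilution by more immune cells is argued against for the lower genes. The luminal marker median of WT 2 differed from that of WT 1 and WT 3 by only −0.67 on the log2 scale. Cyp26a1 was at 5.61 FPKM in WT 2 against 239 and 160 in WT 1 and WT 3, and Areg at 14.8 against 191 and 210. For both genes WT 2 lay within the range of the knockout libraries (4.17 to 18.9 and 4.62 to 43.3 FPKM). Apart from cell makeup, no biological explanation for WT 2 was tested.

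The 6 libraries can be divided into 3 and 3 in 10 ways, the real division included, too few for a share under 0.05. Genes at the adjusted threshold numbered 0 by limma in all 10 splits (in the real one 1944 passed unadjusted). For genes at an unadjusted p under 0.05 the real value was 1944 and the highest other 2008, so 2 of the 10 splits, the real one included, had as many, and the other of them set WT 1, WT 3 and Igf1rKO 3 against the rest. Lists called by camera numbered 12 in the real split and up to 14 in others, with as many in 6 of the 10 splits, the real one included. A count of this size therefore did not mark out the real division. Over the list alone, 1 split, the real one, had as many calls for cell cycle (34, highest other 0), cholesterol (10, highest other 2), FOXO (3, highest other 0) and gland genes (8, highest other 5). These lists had the most such calls in the real split, so the choice of lists favours that split. The lists with the most calls in each other split were not compared.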
